A study of Mus with 6 samples.

How the data were processed

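RNA sequencing of cardiac microvascular endothelial cells from mice after ligation of the left coronary artery was used, with 3 wild-type (WT) and 3 Ccl28 knockout (KO) libraries. Per the labels' protocols, CD45-negative CD31-positive cells were isolated with magnetic beads, RNA was extracted with TRIzol, and libraries were made from 1 µg of total RNA with a TruSeq stranded mRNA kit. Groups and replicate numbers were taken from the sample titles. The genotype field of the KO libraries with numbers 3 and 4 names Ccl29 and Ccl30 in place of Ccl28, in conflict with their titles, and the titles were followed. No strain, sex, age, batch or time after ligation was given in the sources used here. Nothing says that the replicates are separate animals, so p-values measure only the spread between these samples, which may be technical.

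FPKM values per gene and library were deposited by the authors for 20893 genes. A second table of 17686 genes, deposited by the authors, holds the mean normalized signal of each group, the fold change as a ratio, the log2 fold change and the p-value and q-value of their DESeq2 comparison, per the file headers. The mm10 build, fastp 0.19.3, HISAT2 2.1.0, StringTie 1.3.4d, Cufflinks, featureCounts 1.6.2, DESeq2 1.22.1 and GATK 4.0.11.0 are named, without role or order, per the submitters' processing notes. Gene IDs were matched to the NCBI annotation of GRCm38.p6 for coordinates, and 20334 of 20893 matched.

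The values used were FPKM, so the main test was not made on read counts per library. Ratios of FPKM to the group means of the authors' deposited table gave the library factors (median relative residual 6.7e-11), and from these the whole reads behind each value. Of values up to 1000 reads, 100.0% were whole within 0.05 reads. The recovered reads gave the depth (40500067, 39104282 and 39431772 reads in WT replicates 2, 3 and 4, and 37780513, 37181289 and 36004457 reads in KO replicates 2, 3 and 4), an implied transcript length per gene, and floors, which cover counting error only. A further 3207 genes were outside the comparison table and had no recovered reads. Replicates of a group differed by 19.5 to 66.7 in chi-square per gene, so none was the same library deposited again.

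Genes with FPKM of at least 1 in at least 3 libraries were tested with limma 3.58.1 (R 4.3.3, trend, genotype only) on log2(FPKM + 1), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Folds named in the text are ratios of mean FPKM. A count model was planned for the case of read counts, and the test planned for FPKM was used. Ccl28, Ccr10, Ccr3 and Ccl27a were compared with exact two-sided permutation tests, and a gene with 0 reads was set to a floor of 3 reads per library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

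The main test, the gene lists, the rule for named genes and the first set of other settings were chosen before the data were examined. The rule named the 4 genes above; the 15 higher and 15 lower genes with the smallest p whose groups did not overlap, with a mean FPKM of at least 1 in a group and no predicted-gene name; up to 4 members per list with the smallest p; and up to 4 called members of an enriched term. A gene that the rule selects is not reported here. The 31 lists, with 573 of 581 symbols found, were the CCL28 axis, pan-endothelial identity, angiogenesis and tip cell, Notch signalling, arterial, venous, capillary and lymphatic endothelium, endocardium, flow and nitric oxide, proliferation, leukocyte adhesion, interferon response, antigen presentation, hypoxia and glycolysis, oxidative phosphorylation, fatty acid oxidation, extracellular matrix and EndMT, apoptosis and p53 targets, immediate early and heat shock, chemokines and their receptors, markers of cardiomyocytes, fibroblasts, mural cells, monocytes and macrophages, neutrophils, lymphocytes, erythroid cells and platelets, mesothelial and Schwann cells, sex-linked genes, and mitochondrially encoded mRNAs. Some genes belong to several lists, such as Selp, Sele and Vcam1 (venous and leukocyte adhesion) and Postn and Col3a1 (matrix and fibroblast). Kdr is in the pan-endothelial and angiogenesis lists. Results of lists that share members are therefore not separate evidence. The 29 lists with at least 3 tested members were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists), with an estimated correlation and with fry beside it. With an estimated correlation none of the 29 lists passed camera. KEGG and GO terms of 10 to 500 tested genes, as the authors' deposited annotation gives them, were tested with a one-sided Fisher exact test, adjusted per source and direction.

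Other settings fixed beforehand were quantile normalization, no expression filter, FPKM of at least 5, a pseudocount of 0.1, the replicate number as a block, each library left out in turn, and an added log2 fold change of at least 1. Chosen after seeing the data were median-ratio scaling, removal of a loess trend (span 0.5) on log2 implied length from each library, limma-voom on the recovered reads, and the authors' q-values over the same genes. On simulated reads for KO against WT (10696 genes, 200 changed), the test recovered 88% of 1.5-fold and 100% of 2-fold changes and called 6 unchanged genes. With a simulated length trend (10668 genes) it called 1931 unchanged genes, and 22 once the trend was removed. The simulated genes varied independently, with the same dispersion (0.01) for every gene and the same length slope (size 0.2) in every KO library. The real libraries may vary otherwise, so these numbers need not carry over to them. Genes of near-identical families, such as Dynlt1b, are given as uncertain, and GC content was not examined.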

Results

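The expression of 20893 genes was measured by RNA sequencing in 6 libraries of mouse cardiac microvascular endothelial cells. The cells were taken with magnetic beads as CD31-positive and CD45-negative, CD31 being the endothelial surface protein encoded by Pecam1 and CD45 the leukocyte surface protein encoded by Ptprc. All hearts had undergone ligation of the left coronary artery, which causes a myocardial infarction. 3 libraries came from wild-type (WT) mice and 3 from mice without Ccl28 (KO), and both groups carry the replicate numbers 2, 3 and 4. The values are FPKM, fragments scaled to transcript length and library size, as deposited. The WT libraries held 39104282 to 40500067 reads assigned to genes and the KO libraries 36004457 to 37780513. Levels are given as mean FPKM ± SD with n = 3 per genotype, and log2 fold changes are KO over WT on the log2(FPKM + 1) scale, which understates the change of low genes.

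The targeted gene was examined first. Ccl28, a chemokine of mucosal tissues and a ligand of the receptors Ccr10 and Ccr3, has gene ID 56838 and lies on chromosome 13 from 119623819 to 119654359 (GRCm38). It had 16, 11 and 24 reads in the WT libraries with replicate numbers 2, 3 and 4, and 0 reads in each of the 3 KO libraries. WT expression was therefore low, at 0.1 ± 0.039 FPKM. With a floor of 3 reads per KO library, Ccl28 was at least 5.0-fold lower in KO, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 samples allow. In the authors' deposited table its log2 fold change was -6.36 with q = 0.000497. Ccr10 was detected at 0.369 ± 0.13 FPKM in WT and 0.284 ± 0.103 in KO, with 14 to 36 reads per library, and the difference lay within the spread between replicates (exact permutation p = 0.5). Ccl27a, which encodes the other ligand of Ccr10, had 0.786 ± 0.168 FPKM in WT and 1.41 ± 0.549 in KO (exact permutation p = 0.2). Ccr3 had 0.005 FPKM on average in both genotypes. All members of the CCL28 axis list lay under the expression filter of the main test. Without that filter, limma gave Ccl28 an adjusted p of 0.0239, and an adjusted p of 0.0878 with the replicate number as a block.

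The main comparison, KO against WT, asks how transcripts of these bead-sorted preparations from the infarcted heart differ when Ccl28 is missing. The immediate early genes Egr1, Fos and Jun, the vascular endothelial growth factor (VEGF) receptor gene Kdr, the Notch ligand gene Dll4 and the collagen gene Col1a2 were lower in KO. The MHC class II gene H2-Aa, the leukocyte genes S100a8 and Cd79a, and most ribosomal protein genes were higher. The share of other carried-over cell types was not measured, so a change need not lie within endothelial cells. Of 10806 tested genes, 4772 (44.2%) passed an adjusted p of 0.05 in limma, 1982 of them higher and 2790 lower in KO. With median-ratio scaling the split was 2575 higher and 2390 lower. Most changes were small: 40 higher and 60 lower genes also changed by at least 1 on the log2 scale. The first principal component held 70.4% of the variance, with the WT libraries between -22.28 and -16.85 and the KO libraries between 14.93 and 25.62. The slope of each library on log2 implied transcript length also split the groups, at 0.101 to 0.135 in WT and -0.155 to -0.091 in KO. Replicate 4 was the most extreme library of its group in both measures. Genotype and the length trend therefore cannot be told apart on this component.

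The size and sign of the changes followed transcript length. Among the 2162 tested genes with the shortest transcripts, up to 1791 nt, 1293 rose, 34 fell and the median log2 fold change was 0.35. Among the genes with the longest, 6233 nt and more, 25 rose, 1431 fell and the median was -0.38. Across the 10806 genes, which are not independent replicates, Spearman's rho between length and log2 fold change was -0.72. When a length trend was removed from each library, 2083 genes passed, 1089 higher and 994 lower, and 1410 of these were among the 4772 with the same direction. Counts with that trend removed are given beside each gene list. Camera tests with the trend removed used the preset correlation of 0.01 only. Their adjusted p-values treat the members of a list as nearly independent and may be too small. In the main test the estimated correlation was, for example, 0.815 for the monocyte and macrophage list. Reads of mitochondrial genes took 6.03%, 10.8% and 7.86% of a library in WT and 10.5%, 11.98% and 12.7% in KO, so the groups overlapped, and reads of ribosomal protein genes took 3.94% to 4.38% in WT and 6.02% to 6.81% in KO.

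**Figure D1:**
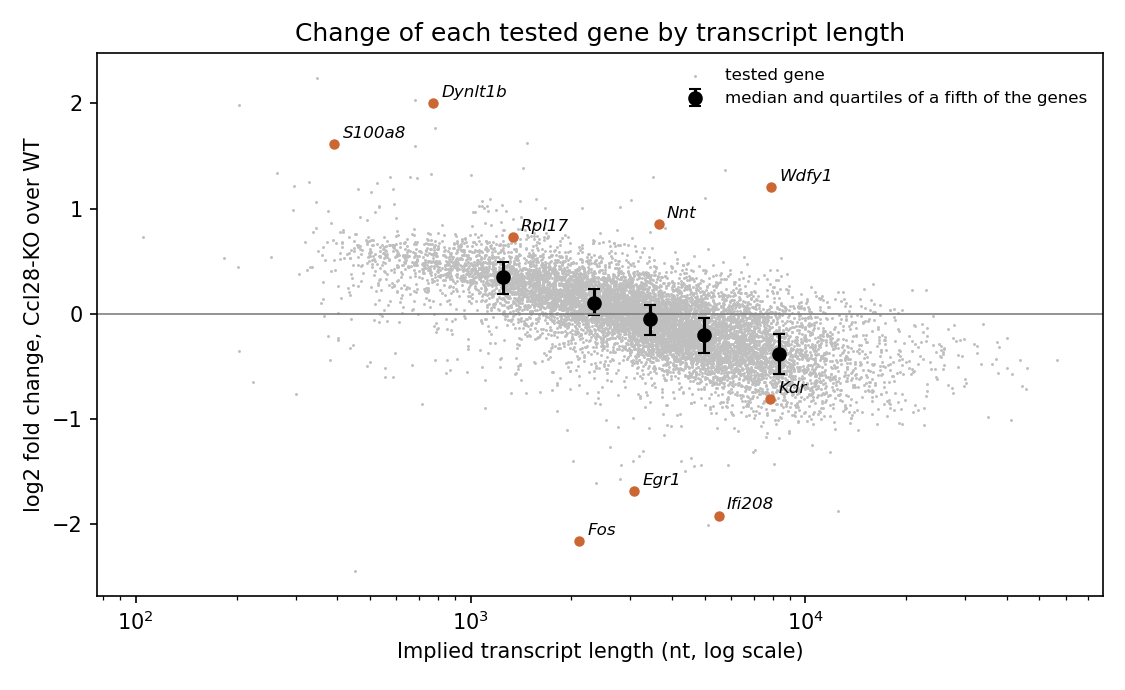
Log2 fold change of each tested gene, KO over WT (y axis), against implied transcript length in nt on a log scale (x axis). Black points and bars are the median and quartiles of each of 5 length classes, which run from 0.35 for the shortest to -0.38 for the longest, and orange points are named genes such as Fos at -2.16 and Wdfy1 at 1.21.

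Immediate early genes, which cells induce within minutes of a stimulus, were lower in KO. The list of immediate early and heat shock genes had 22 tested members, of which 14 fell and 1 rose, with a median log2 fold change of -0.58. Egr1 went from 68.9 ± 3.04 FPKM in WT to 20.8 ± 2.42 in KO (adjusted p = 2.12e-05), Fos from 19.5 ± 3.45 to 3.54 ± 0.314, Nr4a1 from 17.5 ± 2.27 to 3.59 ± 0.633 and Jun from 117.2 ± 17.3 to 45 ± 3.56. Arc and Sik1, which respond to calcium and cAMP signals, fell 3.94-fold and 2.79-fold. Hspb1, named after its values were seen, was the member that rose, from 217 ± 10.1 to 255.5 ± 7.75 FPKM (adjusted p = 0.0208). Its call was lost without KO replicate 2 (adjusted p = 0.0643) or KO replicate 4 (adjusted p = 0.0637), with quantile normalization (adjusted p = 0.558) or with the replicate number as a block (adjusted p = 0.0709), and with the length trend removed its log2 fold change was -0.16. The camera test gave the list an adjusted p of 4.95e-05, against an adjusted p of 0.455 with an estimated correlation, and 15 fell adjusted over the list alone. After removal of the length trend 14 members fell and the median was -0.72 (camera adjusted p = 2.97e-13 with the preset correlation). The estimated correlation between members was 0.376 before that removal.

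In the angiogenesis and tip cell list, 18 of 30 tested members fell and 2 rose, with a median log2 fold change of -0.49. Kdr, the main VEGF receptor of endothelium, fell from 260.5 ± 22.1 to 149.1 ± 25.3 FPKM (log2 fold change -0.81, SE 0.12, adjusted p = 0.000898). Its co-receptors Nrp1 and Nrp2, which also bind semaphorins, fell 1.98-fold and 2.04-fold, and the netrin receptor gene Unc5b, a tip cell marker, fell 1.76-fold. Camera gave the list an adjusted p of 0.000694, and an adjusted p of 0.455 with an estimated correlation. Adjusted over the list alone, 19 fell and 3 rose. After removal of the length trend 15 fell and none of the 30 rose in limma, and Kdr had a log2 fold change of -0.46 (adjusted p = 0.0175). The log2 fold change of Nrp1 went from -0.973 to -0.573 with that removal, and that of Nrp2 from -1.009 to -0.645.

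Notch pathway genes moved in both directions. Of 15 tested members of the Notch list, 8 fell, among them Notch1 (50.7 ± 4.62 to 24.7 ± 3.38 FPKM), the ligand genes Dll4 (147.2 ± 9.54 to 95.8 ± 4.82), Dll1 and Jag1, and 3 rose, including Lfng, a glycosyltransferase of Notch receptors, and the target gene Hes1, both named after their values were seen. Lfng rose from 19.6 ± 2.04 to 28.9 ± 2.42 FPKM and Hes1 from 22.9 ± 1.37 to 31.6 ± 2.93. The list had a camera adjusted p of 0.0367, and an adjusted p of 0.455 with an estimated correlation; 9 fell and 3 rose adjusted over the list alone. Its call was lost without WT replicate 3 (adjusted p = 0.0662), among members with FPKM of at least 5 (adjusted p = 0.0504) and with the length trend removed (adjusted p = 0.0603), where 4 members fell and 2 rose. The log2 fold change of Notch1 went from -1.015 to -0.621 with that removal.

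**Figure D2:**
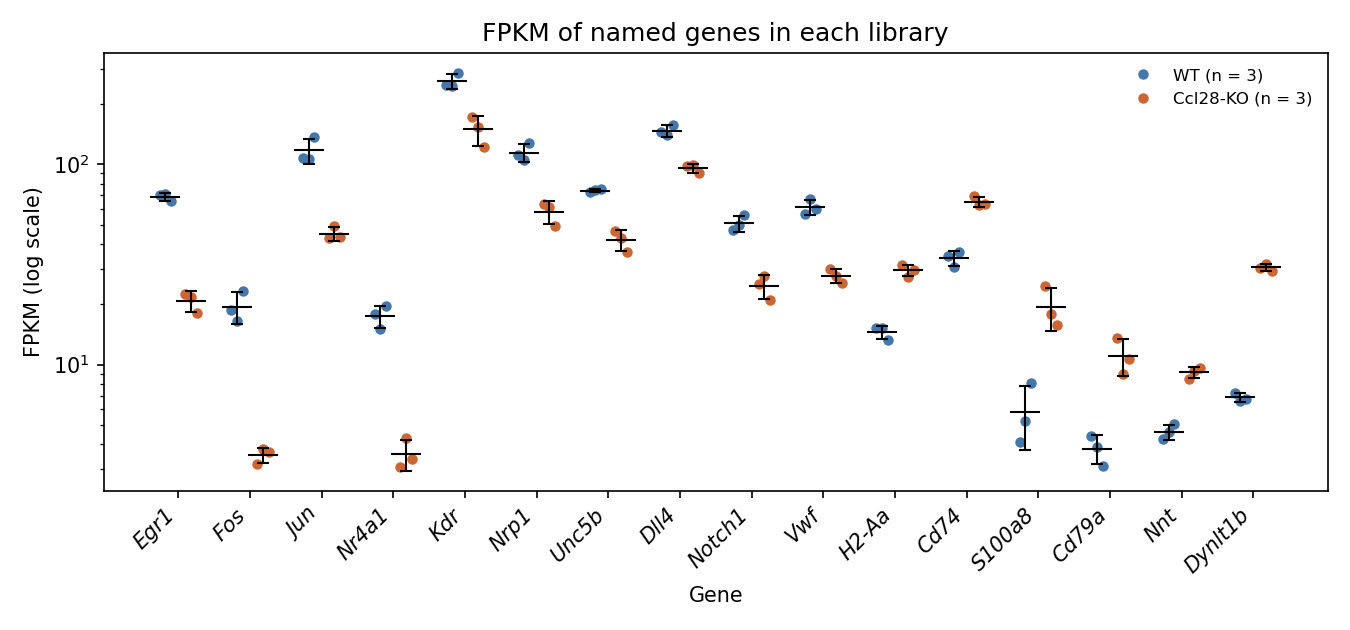
FPKM of 16 named genes (y axis, log scale) in each of the 3 WT libraries (blue points) and 3 KO libraries (orange points), with black lines for the mean ± SD. Every KO library lay below every WT library for the first 10 genes, such as Egr1 and Kdr, and above for the other 6, such as H2-Aa and Nnt.

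Markers of vessel subtypes differed between lists. In the venous list 8 of 11 tested members fell and 1 rose, led by Vwf, the von Willebrand factor gene (61.1 ± 5.49 to 27.7 ± 2.16 FPKM), and the leukocyte adhesion genes Selp (1.85-fold lower) and Sele (1.84-fold lower). The venous list passed camera with an adjusted p of 0.00973 (0.455 as adjusted p with an estimated correlation), and 7 members fell and none of the 11 rose with the length trend removed. In the lymphatic list 5 of 9 fell and none rose in limma, with Mmrn1 at 7.26 ± 1.14 against 2.08 ± 0.784 FPKM and Lyve1 at 10.4 ± 1.66 against 3.89 ± 1.66 (camera adjusted p = 0.00615, and adjusted p = 0.455 with an estimated correlation). In the endocardium list 6 of 8 fell and none rose in limma, including Cgnl1 (24.7 ± 0.712 to 12.4 ± 1.32 FPKM) and Npr3 (camera adjusted p = 0.0106, and adjusted p = 0.455 with an estimated correlation). The endocardium call was lost without WT replicate 3 (adjusted p = 0.0853) and among members with FPKM of at least 5 (adjusted p = 0.0504). Adjusted over the list alone the venous and lymphatic counts were the same, and in the endocardium list 7 fell and 1 rose. With the length trend removed 8 lymphatic (adjusted p = 2.36e-05) and 4 endocardial markers fell (adjusted p = 0.00685).

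The remaining endothelial lists did not pass camera. Of 20 pan-endothelial genes 9 fell, such as Ptprb, a phosphatase of endothelial junctions (103.8 ± 7.66 to 55.9 ± 6.34 FPKM), and Mmrn2, and 5 rose, such as the transcription factor gene Sox18 (305.2 ± 11.1 to 436.1 ± 20.8), with camera adjusted p = 0.281; 11 fell and 5 rose adjusted over the list alone. The pan-endothelial list passed as lower with the length trend removed (6 fell, 2 rose, adjusted p = 0.0277) and with quantile normalization (adjusted p = 0.000314). Removal of that trend took the log2 fold change of Ptprb from -0.886 to -0.421 and that of Sox18 from 0.513 to 0.287. Of 16 arterial genes 5 rose, led by the connexin gene Gja4 (48.6 ± 2.89 to 80.9 ± 8.16 FPKM), and 4 fell, including Jag1, Efnb2 and Depp1 (camera adjusted p = 0.726, the same counts adjusted over the list alone). The median of the arterial list was 0.07 and camera pointed up, while its mean was -0.04 and its median was -0.01 without KO replicate 2, -0.05 with quantile normalization and -0.025 with the length trend removed (3 rose, 5 fell, adjusted p = 0.863). Of 20 capillary and lipid uptake genes 9 rose and 4 fell (camera adjusted p = 0.0538, the same counts adjusted over the list alone). In it Lpl, the lipoprotein lipase gene, fell from 125.9 ± 8.83 to 72.2 ± 8.21 FPKM and Btnl9 fell 1.63-fold, while Fabp5, a fatty acid binding protein gene, rose from 433.2 ± 40.8 to 647.7 ± 8.38. The median of the capillary list was 0.29, and -0.05 with quantile normalization. The list passed without WT replicate 3 (adjusted p = 0.0176) or KO replicate 3 (adjusted p = 0.0328), with the replicate number as a block (adjusted p = 0.0466), without an expression filter (adjusted p = 0.0335) and with limma-voom (adjusted p = 0.0498). Once the length trend was removed 2 capillary genes rose and 3 fell (adjusted p = 0.402). Of 17 flow-responsive and nitric oxide genes 5 fell, including the shear stress factor Klf2 (267 ± 27.9 to 169 ± 18.5 FPKM) and Thbd, and 1 rose (camera adjusted p = 0.342, the same counts adjusted over the list alone). Of these 17 genes 3 fell with the length trend removed (adjusted p = 0.307).

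The lists of matrix genes and mural cell markers were lower in KO, and the fibroblast list did not pass. Of 24 tested genes of the extracellular matrix and EndMT list (endothelial to mesenchymal transition), 13 fell and 2 rose, and 14 fell and 4 rose adjusted over the list alone. Col6a1 went from 4.28 ± 0.458 to 1.53 ± 0.29 FPKM, Postn from 5.19 ± 0.936 to 1.9 ± 0.278 and Col1a2 from 7.62 ± 0.74 to 3.52 ± 0.826, while S100a4, a calcium-binding protein gene named after its values were seen, rose 1.95-fold. Camera gave this list an adjusted p of 0.0259, and an adjusted p of 0.455 with an estimated correlation. The call was lost without KO replicate 2 (adjusted p = 0.0538), and among members with FPKM of at least 5 the median was 0.05 (adjusted p = 0.621). Once the length trend was removed 8 matrix genes fell (adjusted p = 0.00238). Of 15 markers of mural cells, the pericytes and smooth muscle cells that wrap vessels, 9 fell and none rose in limma, the same adjusted over the list alone. Abcc9 fell from 5.87 ± 1.06 to 1.55 ± 0.219 FPKM, Pdgfrb from 16.5 ± 2.78 to 7.32 ± 2.09 and Notch3 from 18.7 ± 3.35 to 7.88 ± 2.93 (camera adjusted p = 0.0133 for the list, and adjusted p = 0.569 with an estimated correlation). The mural call was lost without WT replicate 3 (adjusted p = 0.06) or KO replicate 3 (adjusted p = 0.0846), and 8 mural markers fell with the length trend removed (adjusted p = 0.000349). Of 9 fibroblast markers 5 fell, including Dcn and Col3a1 (camera adjusted p = 0.086; 5 fell and 1 rose adjusted over the list alone), and this list passed without WT replicate 2 (adjusted p = 0.0319) and with the length trend removed (4 fell, adjusted p = 0.00238).

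The MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 rose 1.92-fold to 2.15-fold in KO. H2-Aa went from 14.6 ± 1.1 to 29.6 ± 1.96 FPKM, H2-Ab1 from 13.3 ± 1.15 to 27.5 ± 2.94, H2-Eb1 from 8.58 ± 0.468 to 18.4 ± 2.92 and Cd74, the invariant chain gene, from 34 ± 2.94 to 65.2 ± 3.65. These 4 genes passed with the length trend removed, with log2 fold changes of 0.64 to 0.79. In the whole list 8 of 14 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.00265, and adjusted p = 0.461 with an estimated correlation). With the length trend removed 4 rose and 1 fell (camera adjusted p = 0.0698), and with quantile normalization the adjusted p was 0.262. Some markers of leukocytes, of which several kinds carry MHC class II, rose as well. The B cell receptor genes Cd79a (3.81 ± 0.629 to 11.1 ± 2.3 FPKM) and Cd79b (3.38 ± 0.337 to 7.13 ± 1.54) were among 3 of 4 tested lymphocyte markers that rose (camera adjusted p = 0.0133). Of 7 neutrophil markers 4 rose, led by S100a8 (5.8 ± 2.06 to 19.5 ± 4.71 FPKM) and S100a9 (9.24 ± 0.893 to 23.7 ± 5.74; camera adjusted p = 0.00867). Of 20 monocyte and macrophage markers 9 rose and none fell in limma, with the complement gene C1qc at 8.04 ± 2.87 against 16.9 ± 2.21 FPKM (camera adjusted p = 0.00221). With the length trend removed 3 lymphocyte, 3 neutrophil and 2 of the 20 monocyte and macrophage markers rose (adjusted p = 0.0165, 0.0203 and 0.00238 for the lists). The neutrophil call was lost among members with FPKM of at least 5 (adjusted p = 0.0835). With an estimated correlation the lymphocyte and neutrophil lists had an adjusted p of 0.455 and the monocyte list an adjusted p of 0.569. The lymphocyte and neutrophil counts were the same adjusted over the list alone, and 10 monocyte markers rose on that basis. Ptprc, which encodes CD45 and is named after its values were seen, was at 1.23 ± 0.438 FPKM in WT and 1.16 ± 0.213 in KO (adjusted p = 0.895).

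Inflammatory genes of the endothelium and interferon-induced genes did not pass as lists in the main test. Of 20 leukocyte adhesion and inflammatory endothelium genes 8 fell and 1 rose (camera adjusted p = 0.086), the same adjusted over the list alone. The chemokine gene Cxcl10 fell from 12 ± 3.35 to 5.88 ± 0.427 FPKM and the adhesion molecule gene Vcam1 from 26.7 ± 3.24 to 19.5 ± 1.08. After removal of the length trend 9 fell and the list passed (adjusted p = 0.00267), as it did without an expression filter (adjusted p = 0.028) and at FPKM of at least 5 (adjusted p = 0.0419). Of 26 interferon response genes 7 fell, including Gbp7 and Rsad2, and 1 rose (camera adjusted p = 0.271); 6 fell and none of the 26 rose adjusted over the list alone. The interferon list passed as lower without WT replicate 4 (adjusted p = 0.03) and with the length trend removed (3 fell, 1 rose, adjusted p = 0.0148). Of 19 chemokines and chemokine receptors 5 rose, including Ccl6 (10.8 ± 5.87 to 27.1 ± 4.38 FPKM), and 3 fell, including the scavenging receptor gene Ackr3, which fell 1.46-fold (camera adjusted p = 0.18 for the list, the same counts adjusted over the list alone). Of these 19 genes 2 rose and 3 fell with the length trend removed (adjusted p = 0.985).

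Most ribosomal protein and respiratory chain genes rose. Of 132 tested genes of the KEGG Ribosome term 122 were higher in KO (one-sided Fisher exact adjusted p = 9.22e-71), for example Rpl17 (309.1 ± 12.4 to 514 ± 42.7 FPKM), and this enrichment held with the length trend removed (adjusted p = 3.34e-15). Of 32 genes of the oxidative phosphorylation list 27 rose and none fell in limma, such as the cytochrome oxidase gene Cox6c (226.5 ± 8.07 to 341.5 ± 13.6 FPKM) and the complex I gene Ndufc1 (35.9 ± 1.65 to 58.3 ± 5.23); 28 rose adjusted over the list alone. Camera gave the list an adjusted p of 3.75e-11, and an adjusted p of 0.455 with an estimated correlation. With the length trend removed its median went from 0.45 to 0.04, 4 rose and the call was lost (adjusted p = 0.0698). Of 13 mitochondrially encoded mRNAs 8 rose, the same adjusted over the list alone, with ATP6 at 212.8 ± 82.4 against 869.6 ± 288.7 FPKM and COX3 at 654.8 ± 48.3 against 2389 ± 1019 (camera adjusted p = 0.000383, and adjusted p = 0.455 with an estimated correlation). The mitochondrial list missed the threshold with quantile normalization (adjusted p = 0.0749), and 4 of its members rose with the length trend removed (adjusted p = 0.00685). Of 17 fatty acid oxidation genes 4 rose and none fell in limma (camera adjusted p = 0.0538), 2 of them adjusted over the list alone, with Etfb at 79.6 ± 8.35 against 111.7 ± 13.7 FPKM. The fatty acid oxidation list passed without KO replicate 3 (adjusted p = 0.0182), with median-ratio scaling (adjusted p = 0.0373), with limma-voom (adjusted p = 0.0301) and without an expression filter (adjusted p = 0.0249). Once the length trend was removed 2 of its members rose (adjusted p = 0.376).

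The lists for cell division, glucose use and cell death did not pass camera. Of 26 proliferation genes 4 rose, such as Ube2c (10.2 ± 2.27 to 16.5 ± 2.32 FPKM) and Tyms (4.91 ± 0.727 to 6.84 ± 0.419), and 1 fell (camera adjusted p = 0.17); adjusted over the list alone 3 rose. This list passed without WT replicate 2 (adjusted p = 0.00132), and its median of 0.11 was -0.02 without WT replicate 3. Of the proliferation genes 3 rose with the length trend removed (adjusted p = 0.232). Of 25 hypoxia and glycolysis genes 5 fell, including Epas1, which encodes the hypoxia factor HIF-2α (418.8 ± 39.6 to 303.2 ± 26.8 FPKM), and 2 rose, led by Gpi1 (132 ± 6.87 to 168.9 ± 8.81; camera adjusted p = 0.726); adjusted over the list alone 4 fell and 2 rose, and with the length trend removed 3 rose and 1 fell (adjusted p = 0.47). Of 19 apoptosis and p53 target genes 8 fell, including Eda2r (3.87 ± 0.387 to 1.79 ± 0.278 FPKM) and Gdf15, and 2 rose (camera adjusted p = 0.0805). Adjusted over the list alone, 8 fell and 3 rose. The median of the apoptosis and p53 list was -0.31, and it passed without KO replicate 3 (adjusted p = 0.032), without an expression filter (adjusted p = 0.0473) and in fry, which asks only whether its genes move one way (adjusted p = 0.0279). Once the length trend was removed 4 fell and 1 rose (adjusted p = 0.0766).

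**Figure D3:**
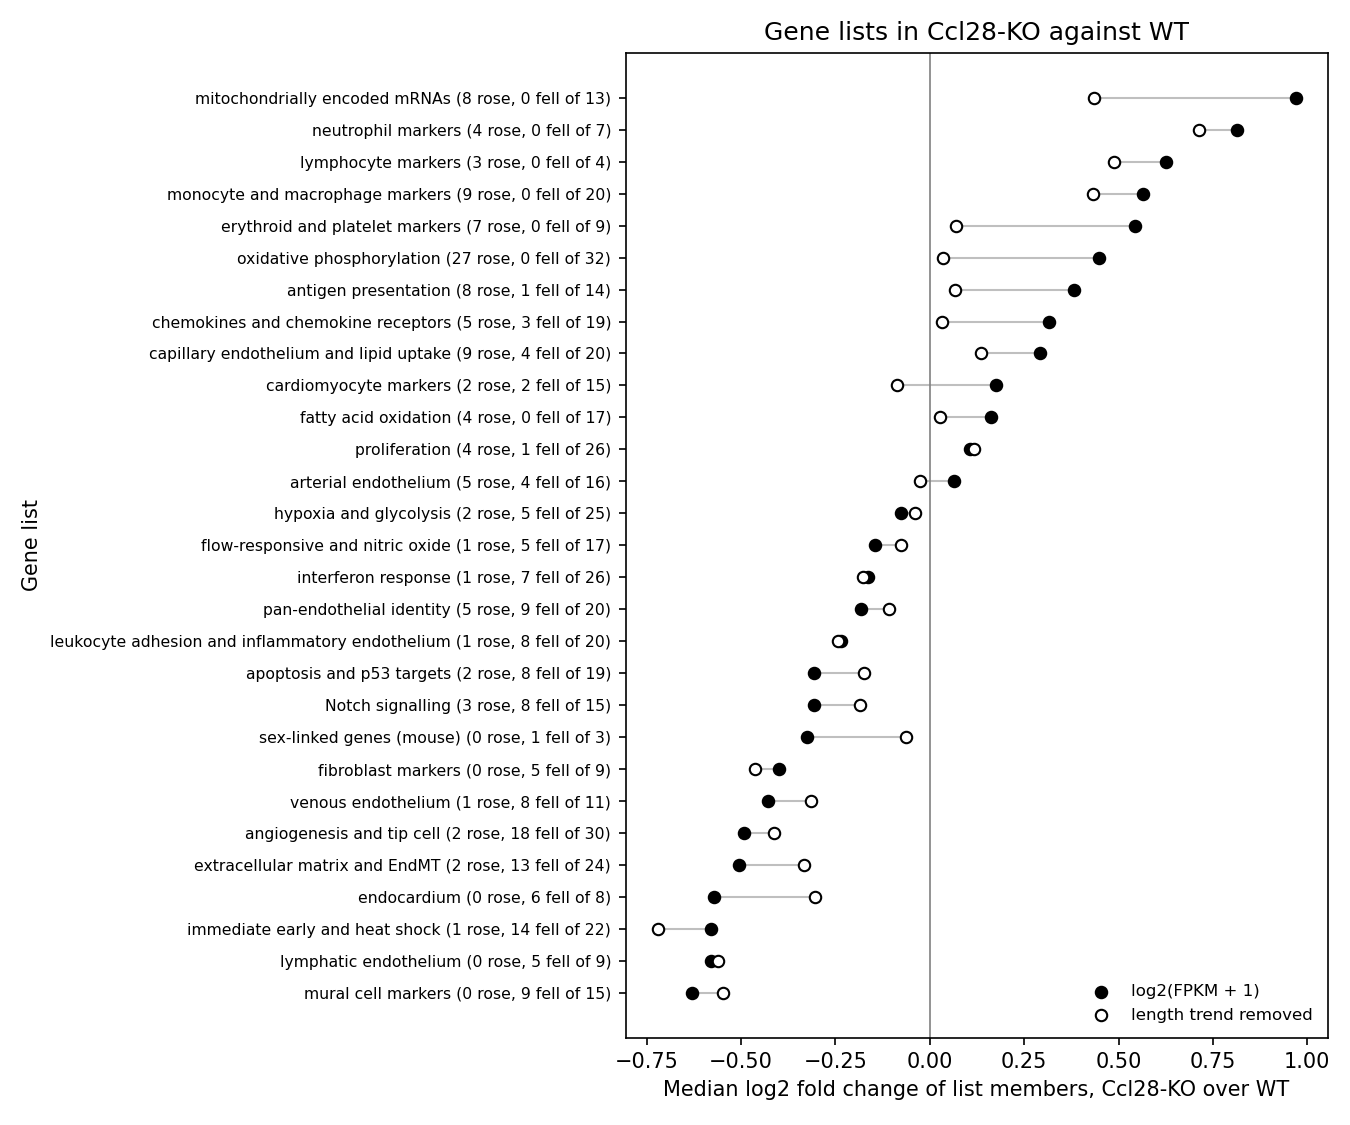
Median log2 fold change of the tested members of each of 29 gene lists, KO over WT (x axis), on the log2(FPKM + 1) scale (filled points) and with the length trend removed (open points), with the number of members that rose or fell beside each list name. The immediate early list lay at -0.58 and -0.72, and the oxidative phosphorylation list at 0.45 and 0.04.

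Of the other cell types that a CD31 bead sort can carry over, 9 erythroid and platelet markers included 7 that rose, the same adjusted over the list alone, such as the platelet chemokine genes Ppbp (9.41 ± 2.11 to 19.9 ± 2.09 FPKM) and Pf4 (26.3 ± 9.25 to 59.5 ± 11.4; camera adjusted p = 0.00276 for the list, and adjusted p = 0.455 with an estimated correlation). With the length trend removed 2 rose and the list did not pass (adjusted p = 0.121). Of 15 cardiomyocyte markers 2 rose, Nppa and Myl2, and 2 fell, among them Atp2a2 (43.8 ± 3.81 to 23.5 ± 3.32 FPKM; camera adjusted p = 0.256 for the list). Adjusted over the list alone 2 rose and 1 fell, and the median of the list was 0.17, 0.02 without WT replicate 2, 0.26 without WT replicate 3 or 4, and -0.09 with the length trend removed (1 rose, 1 fell, adjusted p = 0.559). The mesothelial and Schwann list had 1 tested gene, Wt1, which fell 1.35-fold (adjusted p = 0.0029, the same adjusted over the list alone, and 0.00768 with the length trend removed), and no group test was made. Y-linked genes were expressed in all 6 libraries and Xist did not reach the filter, and of 3 tested sex-linked genes Ddx3y fell from 9.26 ± 0.83 to 5.68 ± 0.354 FPKM (camera adjusted p = 0.18 for the list); 2 fell adjusted over the list alone, and 1 rose and 1 fell with the length trend removed (adjusted p = 0.687).

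The rule for the smallest p also named genes outside the lists, whose values did not overlap between genotypes. Dynlt1b, a dynein light chain gene, rose 4.46-fold (6.86 ± 0.334 to 30.6 ± 1.12 FPKM, adjusted p = 1.8e-06). Its reads can be shared with the near-identical copies Dynlt1a, Dynlt1c and Dynlt1f, so its level is uncertain. Wdfy1 rose 3.0-fold, the endosomal Rab4a 2.42-fold and the kinase gene Camk2b 7.25-fold, from 0.342 ± 0.136 to 2.48 ± 0.683 FPKM. Nnt, which encodes the mitochondrial nicotinamide nucleotide transhydrogenase, rose from 4.62 ± 0.399 to 9.16 ± 0.623 FPKM and lies on chromosome 13 from 119335527 to 119409257, close to Ccl28. Coro1a, an actin regulator of leukocytes, rose 2.1-fold. Ssr4, Tmem160 and Fis1 rose 1.54-fold to 1.57-fold, and their log2 fold changes of 0.65, 0.62 and 0.61 were 0.25, 0.22 and 0.27 with the length trend removed. The interferon-inducible Ifi208 fell from 2.86 ± 0.447 to 0.0184 ± 0.0278. Bmpr2, a receptor of bone morphogenetic proteins mutated in pulmonary arterial hypertension, fell from 10.8 ± 1.23 to 3.74 ± 0.293 FPKM. The matrix and scaffold genes Hspg2, Fbn1 and Ahnak fell 2.1-fold to 2.16-fold. Their log2 fold changes of -1.1, -1.02 and -1.04 were -0.62, -0.61 and -0.52 with the length trend removed. Plac9a (5.68-fold lower) and Tmem254a (3.41-fold lower) belong to a duplicated region, so their levels are uncertain as well. The genes given here with a fold or a level, and Egr1, Fos, Nr4a1, Arc, Jun, Vwf, Sik1, H2-Aa, H2-Ab1, H2-Eb1, Cd74, Cd79a and Rpl17 named above by the same rule, passed with the length trend removed. Among the genes named by list, the call was lost with that removal for Hes1 (adjusted p = 0.0887), Fabp5 (0.103), S100a4 (0.0755), Cox6c (0.577), Ndufc1 (0.0715), Etfb (0.558), Ube2c (0.16), Epas1 (0.118), Nppa (0.381) and Pf4 (0.0831), besides Hspb1, whose sign turned (0.125). It was lost without an expression filter for Thbd (adjusted p = 0.0643), Ccl6 (0.0698), Nppa (0.0562) and Myl2 (0.0516).

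Annotation terms were tested for all genes called in each direction. Among higher genes 23 of 309 KEGG terms and 88 of 3017 GO terms passed, and among lower genes 92 and 484. Besides the Ribosome term, higher genes were enriched in the KEGG terms Oxidative phosphorylation (90 of 122 genes, adjusted p = 4.96e-35) and Proteasome (33 of 44, adjusted p = 2.89e-13), both with an adjusted p of 1 once the length trend was removed. Lower genes were enriched in ECM-receptor interaction (31 of 42, adjusted p = 1.62e-08) and Focal adhesion (77 of 143, adjusted p = 4.17e-10), which include Vwf, Itga1 and Col6a1, and these had adjusted p values of 1.44e-07 and 0.000614 with the length trend removed. The GO term angiogenesis held 93 lower genes of 190 (adjusted p = 2.84e-09, and 3.52e-10 with the length trend removed). The GO term chromatin organization held 134 lower genes of 275 (adjusted p = 4.77e-13, and 0.146 with the length trend removed). With the length trend removed, 2 KEGG and 15 GO terms passed among higher genes and 33 and 176 among lower genes.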

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

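Median-ratio scaling, removal of the length trend, limma-voom and the authors' q-values were tests chosen after the result was seen. Against 1982 higher and 2790 lower genes, the added fold threshold left 40 and 60. Removal of the length trend gave 1089 and 994, not all of them called in the main test. Higher lists went from 7 to 4, higher KEGG terms from 23 to 2 and higher GO terms from 88 to 15. Lower KEGG terms went from 92 to 33, lower GO terms from 484 to 176 and lower lists from 8 to 11. That setting takes out changes that follow length and also calls genes that the main test did not. It turned Hspb1 to -0.16 (adjusted p = 0.125). Quantile normalization gave 58 higher GO terms, and the cause was not tested. With an estimated correlation camera passed 0 lists in each direction, while fry, which does not compare a list with other genes, passed 13 lower lists in place of 8 and 5 higher lists in place of 7. In fry the mural (adjusted p = 0.101), monocyte and macrophage (0.242) and mitochondrial lists (0.059) missed the threshold. Lists that passed fry as lower but missed camera were pan-endothelial (fry adjusted p = 0.0284), flow and nitric oxide (0.0279), leukocyte adhesion (0.0177) and fibroblast (0.0125). The apoptosis and p53 list (fry adjusted p = 0.0279) and the sex-linked list (0.0279) did so as well. The Ccl28 level was -0.98 with log2(FPKM + 0.1) and -0.14 with log2(FPKM + 1), since a smaller pseudocount shrinks a low gene less. Leaving out each library in turn gave 1397 to 1994 higher genes, 1878 to 2581 lower genes, 7 to 9 higher lists and 5 to 9 lower lists, the 5 without WT replicate 3. Total calls were 3641 without the filter, 3680 at FPKM of at least 5, 4566 with quantile normalization, 4739 with a pseudocount of 0.1, 4965 with median-ratio scaling, 5114 with limma-voom and 4766 by the authors' q-values. The replicate number as a block gave 3749 calls. Same-numbered samples had correlations of -0.195, -0.349 and -0.222, so the numbers were not taken as pairs, and no sample correlated best with its own number. Of 118 single genes followed across settings, 96 kept direction and call with the length trend removed and at least 112 with each other setting that tested all of them. Most of these genes were named for a small p in the same data, so they were likely to keep their calls. Of all 4772 main calls, 1410 kept direction and call with the length trend removed. The count-only alternatives (DESeq2, edgeR scaling) were planned for deposited read counts and were not run. On the recovered reads limma-voom was run in their place. Depth limits Ccl28 and Ccr10, at under 40 reads per library.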

Other observations

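Removal of the length trend and the tests of neighbours of Ccl28 and of the summed Dynlt1 copies were chosen after the result was seen. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes as the real one, the real split itself (4772), the highest other called 0, and the splits are too few for a share under 0.05.

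Short transcripts were higher and long transcripts lower in KO, and outside the ribosomal and respiratory terms Spearman's rho between length and log2 fold change was -0.709 over 10552 genes, which are not independent replicates. The slopes on log2 length ran from 0.101 to 0.135 in the WT libraries and from -0.155 to -0.091 in the KO libraries. This is consistent with a length-dependent loss of RNA or fragments that differed between the sets of libraries, for example in RNA quality. Ribosomal protein genes lay a median of 0.20 (quartiles 0.121 and 0.325) above the 20 genes nearest in length, 120 of 132 above. The implied length is the length behind the FPKM values and not a measured mRNA length, so matching on it may leave part of the trend in place. A rise of this class beyond the trend may add to the trend, but the matching cannot settle it. Genotype itself stays open as an untested cause of the trend and of such a rise.

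Immediate early genes were lower in KO, and after removal of the length trend the median of 16 members was -0.79 (quartiles -1.28 and -0.32), with 12 lower, which argues against the length trend as the whole cause. Less stress from dissociation and sorting in the KO preparations might lower these genes. Heat shock genes, which such stress also induces, had a median of -0.33 (quartiles -1.20 and -0.17) over 6 members after the same removal, 2 of them lower, between the bounds set for and against this explanation, so it cannot be told apart from an effect of genotype. The handling of the samples was not recorded in the sources used here.

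Several single genes differed by large and even amounts, and 3 of the 100 genes with the smallest p, Itga1, Nnt and Tmem267 (the last named after its values were seen), lay within 10 Mb of Ccl28, 10.8 times the share among all tested genes (one-sided Fisher exact p = 0.00263). This count was set up after Nnt had been seen among these genes, so it partly restates what prompted it, and 15 of the 30 tested genes near Ccl28 were called, against 44.2% of all tested genes. Variants linked to the targeted locus, or an effect of the targeting on its neighbours, stay open as a candidate explanation, since Nnt is mutated in a common C57BL/6 substrain. Strain segments elsewhere stay open too. Among the 100 genes with the smallest p after removal of the length trend, 6 pairs of genes of different families lay within 1 Mb of each other. Families were told apart by the start of the gene symbol. Pairs within a family were counted neither here nor in the random sets. Nnt and Tmem267, at the Ccl28 locus itself, were 1 of these pairs. The 10000 random sets had a median of 9 pairs, with 4 and 15 at the 5th and 95th percentiles (permutation p = 0.88). The bound set beforehand against this explanation, a count at or under the random median, was therefore met. That bound was too loose, because a segment with 1 changed gene adds no pair, and the 5th percentile was used in its place. The 4 Dynlt1 copies summed differed by 1.46 on the log2 scale, so reads moved between counted copies do not account for the rise of Dynlt1b. The sum does not cover reads left uncounted because they match several copies, so the level of Dynlt1b stays uncertain. Genotype stays open for each of these single genes.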
